A study of Mus musculus with 6 samples.

How the data were processed

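RNA was measured in tissue labelled as retinal pigment epithelium (RPE) of mouse embryos at embryonic day 13.5, with 3 arrays for an albino genotype and 3 for a pigmented genotype. Per the labels, each array held tissue pooled from 3 to 4 littermates, and the 3 arrays of a genotype are separate biological samples. The labels' protocols describe an eyecup from which cornea, lens, neural retina and tissue outside the eye were taken away, and biotin-labelled cRNA made from 100 ng of total RNA with a kit that primes from the 3' end. The sample descriptions add that the tissue covers the whole region of the eye, and which of these descriptions holds for the pools was not settled. Markers of other tissues read high on every array, so the pools are not taken as RPE alone. Of the gene lists described below, periocular mesenchyme markers had array means of 10.85 to 11.17 and RPE identity genes 8.23 to 8.52. The erythroid marker Hbb-y read 14.11 to 14.44. Levels of different probe sets do not compare as amounts of tissue. The labels name neither the mutated gene nor the strains.

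The deposited values are log2 RMA expression values, made per the submitters' processing notes with Affymetrix Expression Console 1.1 and RMA. RMA corrects the background, makes the distributions of the arrays alike by quantile normalization and summarises the probes of each probe set. Whether all 6 arrays were normalized in 1 run is not given in the sources used here. The table holds 45101 probe sets with values given to 2 decimals, of which 64 are control probe sets. Median log2 values lay between 5.19 and 5.22 on the 6 arrays. Quantile normalization removes any change shared by all transcripts, so every difference is relative to the other probe sets. The number of arrays limits the precision, with 3 pools a genotype.

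Probe sets were named through the platform annotation given with the table. 34945 probe sets named 1 gene, 932 named several and 9160 had no gene named in the annotation used. Of those with 1 gene, 34754 matched a gene table of assembly GRCm38.p6 by Entrez ID, and 0 symbols changed. Control probe sets and probe sets with a mean below 5 over the 6 arrays were left out, which kept 23591 probe sets and 12098 genes. A gene was represented by its probe set with the highest mean among those naming only that gene, and disagreeing probe sets of a named gene are given beside it.

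Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided), as albino minus pigmented, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. All adjusted p-values of genes and probe sets come from limma. Shifts of 26 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 26 lists. Camera was repeated with an estimated correlation, and fry tested whether the genes of a list moved one way on balance. The lists held 481 entries, of which the annotation used names 453. Members were also adjusted over the list alone. Means of lists over the pools were set against each other by an exact permutation test, whose smallest two-sided p with 3 pools against 3 is 0.1. Differences are log2 values, and errors are SD over 3 arrays or the standard error (SE) of the limma estimate.

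The design, the lists and the rule for named genes were fixed before the data were examined. The rule took the 10 genes past the threshold with the largest rise and the 10 with the largest fall. Where fewer than 5 passed in a direction, it took the 10 genes with the smallest unadjusted p in that direction, as values that did not pass. It always took Tyr, Tyrp1, Dct, Pmel, Mitf, Otx2, Rpe65, Gja1, Axin2 and Lef1. From each list it took up to 4 members past the threshold or, for a list past the camera threshold without such a member, the 2 members with the smallest p. Other genes named in the text were chosen after their values were seen.

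The labels give both genotypes the replicate numbers 1, 2 and 3 without saying what a number shares. Deviations from the genotype means correlated at 0.863 between the arrays numbered 1, at 0.687 between those numbered 2 and at 0.448 between those numbered 3, so the numbers were taken to pair the arrays, from the data and not from the labels. Most of that structure separates replicate 1 from the other arrays. Albino replicate 2 correlated at 0.693 with pigmented replicate 3, and the difference of replicate 2 minus replicate 3 correlated at -0.08 between the genotypes. The fit without a replicate block is the main one, and the blocked result is given where a call differs. Passes reached only with the replicate block rest on this pairing, which replicates 2 and 3 do not bear out by themselves. Errors, confidence intervals and p-values of genes come from the fit without the block unless the block is named. They change with the block, as the SE of Gja1 (0.11 without it, 0.055 with it) and of Myf5 (0.25 and 0.28) show. No 2 arrays were copies of each other, with at most 3.67% of values equal to 2 decimals between any pair.

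Alternatives covered the filter on dim probe sets, cyclic loess and median centring of the deposited values, the replicate block, trended and robust eBayes, array weights, probe sets with IDs ending in _x_at or _s_at, the averaging of probe sets, and leaving out each array in turn. A block for replicate 1 against the other arrays, the fit without both replicate 1 arrays, the replicate block with an estimated correlation, and a covariate for Y-linked transcripts were added after seeing the data.

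The procedure was tested on simulated data with 200 of 23591 probe sets changed. With replicate effects like those of the arrays, the fit without a block recovered 58% of changes of 1 log2 unit and 90% of changes of 2 log2 units, with 0 false calls among 120. With the block it recovered 88% of changes of 0.5 log2 units and 100% of changes of 1 log2 unit, with 26 false calls among 220. The share of false calls among these 220 lay above the adjusted threshold. Without simulated replicate effects the block recovered 0% and 64% of such changes, with 13 false calls among 142. The higher recovery holds only if replicate numbers pair the arrays, which the data bear out only in part. The power of the blocked fit on these arrays may therefore be lower. Camera recovered a list shifted by 0.5 log2 units in both simulated sets, with 0 and 1 other lists called. The estimated list means were 0.31 without replicate effects and 0.56 with them. Noise was drawn for each probe set by itself, so these sets cannot measure false calls of lists whose genes vary together.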

Results

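Gene expression was measured on 6 arrays of tissue labelled as mouse retinal pigment epithelium (RPE), the pigmented layer behind the neural retina, at embryonic day 13.5. The series sets 3 pools from albino embryos against 3 pools from pigmented embryos and asks which transcripts differ between the genotypes. Albinism in mice comes most often from loss of tyrosinase, the enzyme that starts melanin synthesis, but the labels do not name the mutated gene. Pools of a genotype were labelled as separate biological samples. The first principal component held 68.9% of the variance and separated the replicate 1 arrays of both genotypes from the other 4 arrays. The second held 16.9% and separated the genotypes, but its scores also ran with the list means of skeletal muscle markers given below. Albino replicate 3 had the lowest muscle mean of its genotype (8.735) and the score nearest the pigmented arrays (-8.957). Pigmented replicate 3 had the highest muscle mean of its genotype (8.20) and the score nearest the albino arrays (6.33). Only albino replicates 1 and 2, with close muscle means (9.42 and 9.43), broke the order. The second component cannot tell genotype from muscle content. Across probe sets, albino replicate 1 correlated more closely with pigmented replicate 1 (r = 0.99) than with albino replicate 2 (r = 0.973) or 3 (r = 0.974).

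**Figure D1:**
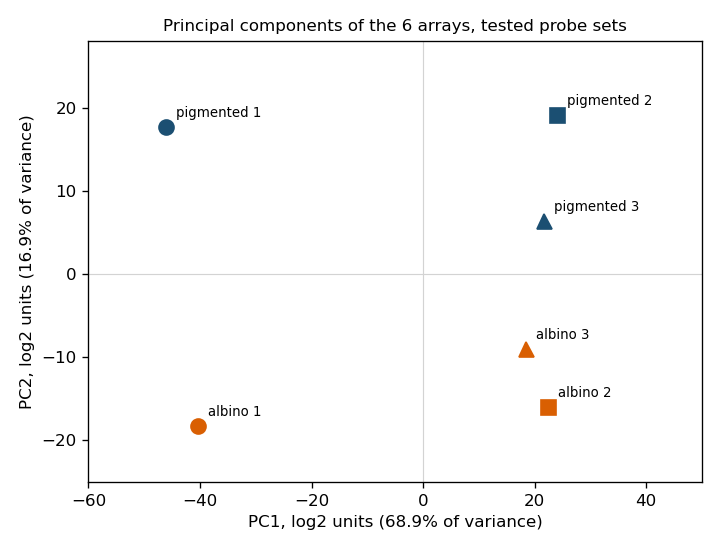
Scores of the 6 arrays on the first and second principal components of the tested probe sets, in log2 units, with colour for genotype and symbol for replicate number. Both replicate 1 arrays lie at negative scores on the first component (-40.4 and -46.1), while the 3 albino arrays lie below 0 and the 3 pigmented arrays above 0 on the second.

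Pigment gene transcripts were abundant in both genotypes. Tyr, which encodes tyrosinase, had a mean log2 level of 10.89 ± 0.13 in albino pools and 11.08 ± 0.18 in pigmented pools (SD, n = 3 each). The arrays read 11.01, 10.75 and 10.91 in albino and 11.24, 11.10 and 10.89 in pigmented pools. The difference was -0.19 (95% confidence interval -0.49 to 0.12, limma adjusted p = 0.999), and the 2 other Tyr probe sets gave -0.06 and -0.37. Many albino alleles leave the transcript in place, so this level does not check the genotype labels. Tyrp1, which encodes a melanosomal enzyme, differed by -0.24 (SE 0.18), Dct, the dopachrome tautomerase gene, by -0.08 (SE 0.11) and Pmel, the gene of the melanosome's fibril protein, by -0.09 (SE 0.13). None of these passed the threshold. Without pigmented replicate 1 Tyr gave -0.11, Tyrp1 -0.078 and Dct -0.0050, and the sign for Pmel turned (0.013).

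The melanin and melanosome list lay slightly lower in albino pools, with 20 of 30 tested members lower and a mean of -0.08. List means were 8.62 ± 0.08 in albino and 8.70 ± 0.11 in pigmented pools (SD, n = 3 each). Camera gave adjusted p = 0.00135 for the shift against all other genes, and adjusted p = 0.709 with an estimated correlation. Differences between arrays of the same number were -0.11, -0.10 and -0.024, and the mean without both replicate 1 arrays was -0.06. Of its members, 0 passed over all probe sets and 0 when adjusted over the list alone. Under the replicate block, 1 passed over the list alone, Slc7a11, the cystine transporter gene, at -0.45 (SE 0.41 without the block). The members with the smallest p were Oca2, which encodes a melanosomal transporter (-0.24, SE 0.10), and Mlana (-0.26, SE 0.11). Skeletal muscle markers were higher in the same pools by a mean of 1.52.

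RPE identity genes also lay lower in albino pools, with 11 of 15 members lower and a mean of -0.10. Ttr, which encodes the thyroxine and retinol carrier transthyretin, stood at 11.69 ± 0.08 in albino and 12.25 ± 0.19 in pigmented pools (SD, n = 3 each), a difference of -0.56. Trpm3, an ion channel gene, differed by -0.32 (SE 0.09), though 1 of its 4 other probe sets had the opposite sign. The transcription factor genes Mitf and Otx2 differed by -0.10 (SE 0.08) and -0.09 (SE 0.15). The second Mitf probe set gave 0.11, and the sign for Otx2 turned without pigmented replicate 2 (0.01) and with the Y-linked covariate (0.09). Rpe65, the retinoid isomerase gene, was below the filter at 3.28 ± 0.20 and 3.17 ± 0.10 (SD, n = 3 each) and was not tested.

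Camera gave adjusted p = 0.00103 for the RPE identity list, and adjusted p = 0.487 with an estimated correlation. Differences between arrays of the same number were -0.12, -0.18 and -0.011, and the mean without both replicate 1 arrays was -0.09. The call was lost with the Y-linked covariate (adjusted p = 0.0710). Over all probe sets 0 members passed. Adjusted over the list alone, 1 passed, and Ttr fell by 0.56 there (adjusted p = 0.0436). Blocking on the replicate number, 4 passed over the list alone, namely Ttr, Trpm3 and the potassium channel gene Kcnj13 (-0.24), all lower in albino, and Serpinf1, the gene of the secreted factor PEDF (0.21), higher. Skeletal muscle markers, described next, were higher in the same albino pools by a mean of 1.52.

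Skeletal muscle markers gave the largest list difference between the genotypes. All 12 tested members were higher in albino pools, with list means of 9.19 ± 0.40 in albino and 7.68 ± 0.47 in pigmented pools (SD, n = 3 each), a mean difference of 1.52 or 2.86-fold. Actc1, the cardiac actin gene also used by embryonic muscle, stood at 12.03 ± 0.41 against 10.32 ± 0.54 (SD, n = 3 each). The muscle regulator genes Myf5 and Myog differed by 1.67 (SE 0.25) and 1.71 (SE 0.29), and Des, the desmin gene, had the smallest difference (0.75, SE 0.26). Adjusted over the list alone, 12 of 12 members passed and rose in albino pools, against 0 over all probe sets.

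The muscle list had a camera adjusted p = 1.02e-21, adjusted p = 1.20e-06 with the replicate block, and adjusted p = 0.382 with an estimated correlation. The exact permutation test of the list means gave p = 0.1, two-sided, the smallest value that 3 pools against 3 allow. Differences between arrays of the same number were 1.86, 2.16 and 0.54, and the mean without both replicate 1 arrays was 1.35.

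**Figure D2:**
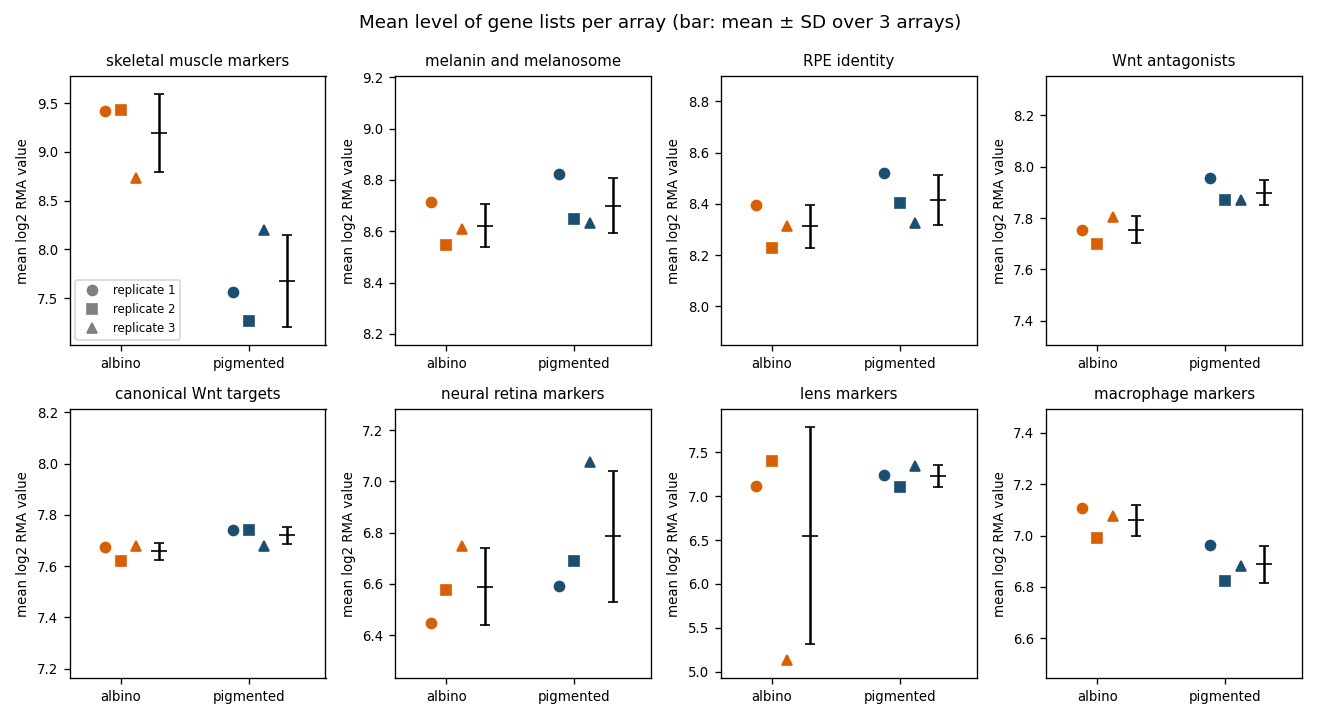
Mean log2 RMA level of 8 gene lists on each array, by genotype, with a symbol for the replicate number and bars for the mean and SD over 3 arrays. Skeletal muscle markers lie between 8.73 and 9.43 on the albino arrays and between 7.27 and 8.20 on the pigmented arrays, while lens markers stand apart on albino replicate 3 alone (5.13).

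Several of the genes with the smallest p on the higher side are known from muscle, and none passed the adjusted threshold. Klhl41 and Myot, which encode sarcomere-associated proteins, differed by 2.03 (SE 0.30) and 1.85 (SE 0.28). Pax7, a transcription factor gene of muscle progenitors, differed by 1.26 (SE 0.19) and Mylk4, a myosin light chain kinase gene, by 1.34 (SE 0.21). Also among the 10 genes with the smallest p on the higher side, with Myf5, were Rrad (1.20, SE 0.16), Arpp21 (1.48, SE 0.22), the transcription factor gene Gata3 (1.43, SE 0.20), the serine protease gene Tmprss11a (1.27, SE 0.18) and Prokr2, a prokineticin receptor gene (0.77, SE 0.10).

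On the lower side, Gfra2, a receptor gene of the GDNF family, stood at 8.58 ± 0.12 in albino and 9.52 ± 0.18 in pigmented pools (SD, n = 3 each). Its other 3 probe sets gave -0.74 to -0.16, and without probe sets ending in _x_at or _s_at its value was -0.21 instead of -0.94. Pik3cd, a phosphoinositide 3-kinase gene, stood at 11.28 ± 0.19 and 12.19 ± 0.24 (SD, n = 3 each). Dpep1 (-0.78), Steap1 (-0.61), the forkhead factor gene Foxf2 (-0.55), the desmosomal cadherin gene Dsc3 (-0.54), Prss23 (-0.53) and Fam162b (-0.51) followed, with Ttr. Kdm6a, an X-linked histone demethylase gene, differed by -0.48 (SE 0.10), in pools whose Xist and Y-linked levels also differed. Its 2 other probe sets gave -0.24 and -0.20. Y-linked means were 7.47, 7.06 and 7.99 on the albino arrays and 7.39, 2.32 and 5.98 on the pigmented arrays.

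No probe set passed, with 0 of 23591 at an adjusted p under 0.05 in limma (smallest 0.50), and 1104 at an unadjusted p under 0.05 where chance gives 1180 if the arrays are taken as unpaired. Without albino replicate 2 the 1104 became 610, and without pigmented replicate 2 it became 567. Of the 1104, 759 were higher and 345 lower in albino pools, or 68.8% higher. That share moved with the scaling, to 31.5% after median centring (486 higher, 1057 lower) and 51.0% after cyclic loess (745 higher, 717 lower). With the replicate block 0 passed (smallest adjusted p = 0.192), and 4243 stood at an unadjusted p under 0.05. The set at an unadjusted p under 0.05 and at least 1.5-fold held 188 higher and 13 lower probe sets, against 147 and 30 after median centring and 163 and 18 after cyclic loess. The 2 genotypes did not overlap at 2556 probe sets, 10.8% against 10% by chance for unpaired arrays, and the 3 other splits that part all pairs gave 1.56% to 4.13%.

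**Figure D3:**
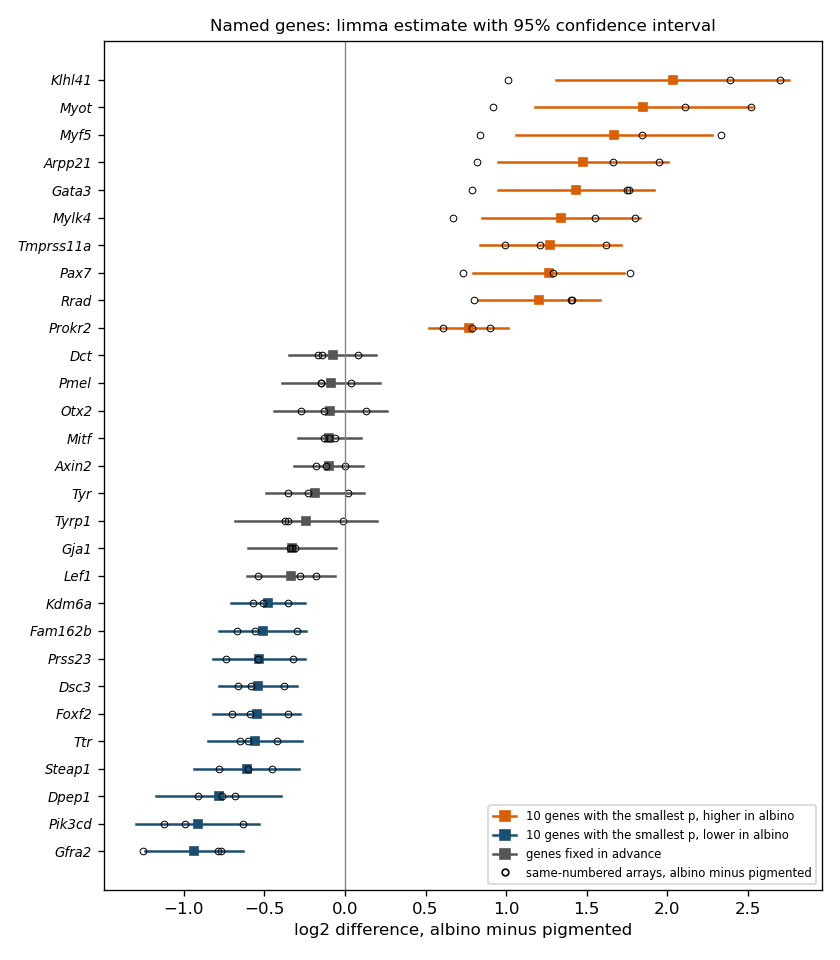
Log2 difference, albino minus pigmented, of the genes named by the rule, with the limma estimate (square), its 95% confidence interval (line) and the differences between arrays of the same number (circles). The estimates run from 2.03 for Klhl41 to -0.94 for Gfra2 (-0.21 without probe sets ending in _x_at or _s_at), and none passed the adjusted threshold.

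Of the 26 gene lists, 11 passed camera, 2 of them higher and 9 lower in albino pools. With the replicate block 11 passed, while 0 passed with an estimated correlation (smallest adjusted p = 0.382) and 0 passed with fry (smallest adjusted p = 0.340). With the Y-linked covariate 3 passed, the skeletal muscle, melanin and melanosome, and Wnt antagonist lists.

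Genes of Wnt signalling were grouped as antagonists, as canonical targets, and as ligands with receptors. Wnt antagonists lay lower in albino pools in 17 of 19 members, with list means of 7.75 ± 0.05 and 7.90 ± 0.05 (SD, n = 3 each) and a mean difference of -0.15. Apcdd1, a membrane inhibitor gene of the pathway, differed by -0.34 (SE 0.11), Nkd2, a Dishevelled-binding inhibitor gene, by -0.32 (SE 0.15) and the secreted inhibitor gene Wif1 by -0.42 (SE 0.22). Without pigmented replicate 1 the value for Nkd2 was -0.16. Camera gave adjusted p = 6.11e-05, and adjusted p = 0.382 with an estimated correlation. Differences between arrays of the same number were -0.20, -0.17 and -0.065, and the mean without both replicate 1 arrays was -0.12. Of its members, 0 passed over all probe sets and 0 adjusted over the list alone, and 1 (Wif1) with the replicate block. Before adjustment the limma p of Wif1 was 0.00087 with that block and 0.0083 with a block for replicate 1 against the other arrays. Skeletal muscle markers were higher in the same albino pools by a mean of 1.52.

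Canonical Wnt target genes lay lower in 11 of 14 members, with a mean of -0.06. Lef1, a transcription factor gene of the pathway, stood at 8.89 ± 0.04 against 9.22 ± 0.18 (SD, n = 3 each), though its other probe set gave -0.0033 and the Y-linked covariate gave -0.20. Axin2, a feedback inhibitor gene, differed by -0.10 (SE 0.09), or by -0.053 without pigmented replicate 2. Camera gave adjusted p = 0.0178, and adjusted p = 0.382 with an estimated correlation. The call was also lost after median centring (adjusted p = 0.112) and cyclic loess (0.104), and without albino replicate 1 (0.237), pigmented replicate 2 (0.131) or pigmented replicate 3 (0.0571). The same held without the filter on dim probe sets (0.184) and with the Y-linked covariate (0.422). Apcdd1, Wif1, Dkk1, Rnf43, Nkd1, Znrf3 and Notum belong to both lists, so the target call is not separate from the antagonist call. The 3 targets higher in albino pools, Lgr5 (0.53), Myc (0.31) and Sp5 (0.26), are not on the antagonist list. Of the target genes, 0 passed over all probe sets and 0 adjusted over the list alone, and 1 (Wif1) with the replicate block.

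Wnt ligands and receptors had 18 of 33 members higher and did not pass as a list (mean 0.08, camera adjusted p = 0.844). Over all probe sets 0 passed, and adjusted over the list alone 2 passed and rose. These were Rspo2, which encodes a secreted enhancer of Wnt signalling (1.21, SE 0.23), and the receptor gene Fzd8 (0.45, SE 0.09), both with adjusted p = 0.0406. Under the replicate block 3 passed over the list alone, with Rspo3 (0.51) added. The muscle markers rose in the same pools.

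Cell junction and polarity genes did not pass as a list (mean 0.0025, 13 of 24 lower, camera adjusted p = 0.295). With array weights the list passed as lower, at a shift from all genes of -0.076 (camera adjusted p = 0.0453). Gja1, which encodes the gap junction protein connexin 43, stood at 12.70 ± 0.12 in albino and 13.03 ± 0.14 in pigmented pools (SD, n = 3 each). Its difference of -0.33 did not pass (limma adjusted p = 0.980), and 1 of its 5 other probe sets had the opposite sign. Over all probe sets 0 members passed, 0 adjusted over the list alone, and 1 (Gja1) over the list alone with the replicate block.

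Neural retina markers had 11 of 14 members lower in albino pools and a mean of -0.20 (camera adjusted p = 0.00226, and adjusted p = 0.505 with an estimated correlation). Rax, a retinal progenitor gene, differed by -0.26 (SE 0.13) while Nefl, a neurofilament gene, differed by 0.60 (SE 0.26). Nefl gave 0.32 without pigmented replicate 2 and 0.21 with the Y-linked covariate, and Rax gave -0.16 without albino replicate 1. The list call was lost without pigmented replicate 3 (adjusted p = 0.564) and without albino replicate 1 (0.231), after median centring (0.0797) and cyclic loess (0.0632), and with the Y-linked covariate (0.125). Over all probe sets 0 members passed and 0 adjusted over the list alone. With the replicate block 6 passed over the list alone, all lower in albino, among them the progenitor genes Sox2 (-0.54), Six6 (-0.52) and Atoh7 (-0.50). These passes depend on the pairing of the arrays. With a block for replicate 1 against the other arrays, Sox2 and Atoh7 missed the threshold even before adjustment. Six6 met it there only narrowly, also before adjustment.

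Ciliary margin markers had 5 of 6 members lower and a mean of -0.16 (camera adjusted p = 0.0386, and adjusted p = 0.452 with an estimated correlation), with Wfdc1 at -0.25 (SE 0.15) and the homeobox gene Msx1 at -0.28 (SE 0.17). Without albino replicate 1 these were -0.12 and -0.43, and Msx1 was -0.16 without albino replicate 2. That call was lost after median centring (adjusted p = 0.136) and cyclic loess (0.104), and without albino replicate 1 (0.233), pigmented replicate 2 (0.323) or pigmented replicate 3 (0.242). It was lost, too, with probe sets averaged (0.0533), without those ending in _x_at or _s_at (0.131), without the filter on dim probe sets (0.184) and with the Y-linked covariate (0.734). Lens markers had 11 of 11 members lower and a mean of -0.68 (camera adjusted p = 0.000141, and adjusted p = 0.539 with an estimated correlation). This rested on albino replicate 3, at a list mean of 5.13 against 7.11 and 7.41 on the other albino arrays and 7.25, 7.10 and 7.35 on the pigmented arrays. Without it the shift from all genes was -0.05 instead of -0.73 (adjusted p = 0.659), and the Y-linked covariate also ended the call (0.0538). The crystallin gene Crybb3 differed by -0.83 (SE 0.63), or by -0.045 without albino replicate 3. Cryab differed by -0.14 (SE 0.11), with its other probe set at 0.013, and by -0.080 without pigmented replicate 3. In both lists 0 members passed over all probe sets and 0 adjusted over the list alone.

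Among vascular and immune cells, macrophage markers were higher in 12 of 14 members, with list means of 7.06 ± 0.06 in albino and 6.89 ± 0.07 in pigmented pools (SD, n = 3 each) and a mean difference of 0.17. C1qc, a complement gene, differed by 0.40 (SE 0.11) and Aif1, a microglia and macrophage gene, by 0.45 (SE 0.16). The camera adjusted p was 0.0162, and adjusted p = 0.505 with an estimated correlation, and the call was lost without albino replicate 3 (adjusted p = 0.128). It was also lost at a mean log2 of at least 6 (0.108), without probe sets ending in _x_at or _s_at (0.130) and with the Y-linked covariate (0.0980). Over all probe sets 0 members passed and 0 adjusted over the list alone. With the replicate block 4 passed over the list alone, all higher in albino, C1qc, Aif1, Ptprc and Tyrobp. Endothelial markers had 9 of 15 members lower and a mean of -0.05 (camera adjusted p = 0.0165, and adjusted p = 0.539 with an estimated correlation), with the transcription factor gene Erg at -0.45 (SE 0.11) and the tight junction gene Cldn5 at -0.19 (SE 0.09). The other Erg probe set gave only -0.057. In that list 0 members passed over all probe sets and 0 adjusted over the list alone, and the call was lost without albino replicate 1 (adjusted p = 0.233) or pigmented replicate 2 (0.380), without the filter on dim probe sets (0.184) and with the Y-linked covariate (0.734).

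Cell cycle genes had 14 of 20 members lower and a mean of -0.04 (camera adjusted p = 0.0178, and adjusted p = 0.820 with an estimated correlation). Mcm2, a replication licensing gene, differed by -0.18 (SE 0.09) and Rrm2, a ribonucleotide reductase gene, by -0.22 (SE 0.12), with 1 of the 2 other Rrm2 probe sets at the opposite sign. Without probe sets ending in _x_at or _s_at these were -0.030 and -0.10, and Rrm2 was -0.12 without pigmented replicate 1. Of its members, 0 passed over all probe sets and 0 adjusted over the list alone, and the call was lost without albino replicate 1 (adjusted p = 0.0543), albino replicate 2 (0.0600), pigmented replicate 1 (0.102) or pigmented replicate 2 (0.0630). It was also lost without probe sets ending in _x_at or _s_at (0.179), without the filter on dim probe sets (0.184) and with the Y-linked covariate (0.0980).

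The remaining lists did not pass camera. BMP and TGF-beta genes had 10 of 18 members higher (mean 0.09, adjusted p = 0.844), and Bmp4, a growth factor gene, rose by 0.50 (SE 0.11) when adjusted over the list alone (adjusted p = 0.0436, 1 member, against 0 over all probe sets). Id1 (0.30) and Bmpr1b (0.40) joined it with the replicate block (3 members). Tyrosine and dopamine metabolism had 3 of 8 members higher (mean 0.01, adjusted p = 0.666), and Ddc, the aromatic amino acid decarboxylase gene, rose by 0.53 (SE 0.09) when adjusted over the list alone (adjusted p = 0.00797, 1 member, against 0 over all probe sets). Maob (-0.21) joined it with the replicate block (2 members). Skeletal muscle markers were higher in the same albino pools by a mean of 1.52.

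In the other 11 lists, 0 members passed over all probe sets and 0 adjusted over the list alone. The camera adjusted p was 0.666 for axon guidance (mean 0.07), 0.99 for the unfolded protein response (0.05), 0.510 for oxidative stress (0.01), 0.99 for lysosome (0.05), 0.335 for hypoxia and glycolysis (0.12) and 0.420 for immediate early genes (0.08). It gave 0.695 for surface ectoderm (0.13), 0.844 for periocular mesenchyme (0.04), 0.844 for erythroid (0.07) and 0.420 for neural crest and melanoblast markers (-0.04). The sex-linked list gave 0.403 (0.98). The erythroid list passed as lower with array weights (adjusted p = 0.0485) and without both replicate 1 arrays (adjusted p = 0.0402). Camera's direction, which is relative to all genes, was lower for the periocular mesenchyme, oxidative stress, cell junction and tyrosine lists, whose means were above 0. It was also lower for the erythroid list, although the mean there lay above that of all genes by 0.026. Under the replicate block, passes over the list alone were Ptch1 (-0.40) and Epha3 (0.79) in axon guidance, Nqo1 (-0.30) in oxidative stress, Egln3 (0.43) in hypoxia and Ednrb (-0.29) in neural crest.

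Linkage to Tyr was tested among the 200 genes with the smallest p, and no difference in share was detected. On chromosome 7, which carries Tyr in assembly GRCm38.p6, lay 17 of these 200 and 890 of 11877 other genes (odds ratio 1.15, 95% confidence interval 0.651 to 1.90, Fisher's exact test, two-sided, p = 0.587). Within 20 Mb of Tyr lay 2 of the 200 and 185 of the others (odds ratio 0.638, 95% confidence interval 0.0762 to 2.37, Fisher's exact test, two-sided, p = 0.773). The first ratio turned without the filter on dim probe sets (0.954).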

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

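The batch block for replicate 1, the fit without both replicate 1 arrays, the replicate block with an estimated correlation and the Y-linked covariate were chosen only after the results were seen. Probe sets past an adjusted p of 0.05 in limma numbered 0 under every alternative, with 201 at an unadjusted p under 0.05 and at least 1.5-fold. Probe sets at an unadjusted p under 0.05 numbered 1104, against 4243 with the replicate block, 4952 with the batch block, 3510 with array weights, 3052 without both replicate 1 arrays and 687 with the Y-linked covariate. They ranged from 567 to 1418 when an array was left out. The smallest adjusted p ranged from 0.0659 with array weights to 1 without albino replicate 2. The replicate block changed no other call than those given with it above. Of 48 named genes, 46 kept their direction in every alternative and 0 passed the threshold in any. Otx2 turned to 0.010 without pigmented replicate 2 and to 0.092 with the Y-linked covariate, and Pmel to 0.013 without pigmented replicate 1. Leaving out an array gave Tyr -0.28 to -0.11. Values of 19 of the 48 genes moved by over 1.5 times or turned under some alternative. The odds ratio on chromosome 7 turned to 0.954 without the filter. No cause was tested except where fewer arrays enter the fit.

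Of 26 lists 11 passed, against 0 with an estimated correlation, 0 with fry, 0 with the replicate block and an estimated correlation, 7 without the filter, 3 with the Y-linked covariate, 13 with array weights, 12 without both replicate 1 arrays and 6 to 10 when an array was left out. Array weights added the cell junction (-0.076, adjusted p = 0.0453) and erythroid (-0.12, adjusted p = 0.0485) lists, and leaving out both replicate 1 arrays added the erythroid list (-0.14, adjusted p = 0.0402), each as lower. The lists that passed kept their direction in every alternative. With the estimated correlation, fry, or both block and estimated correlation, their mean shifts from all genes stayed at 1.47 (muscle), -0.19 (Wnt antagonists), -0.73 (lens), -0.15 (RPE identity), -0.12 (melanin), -0.24 (neural retina), 0.12 (macrophage), -0.10 (endothelial), -0.11 (canonical Wnt targets), -0.087 (cell cycle) and -0.20 (ciliary margin), and none passed. Under cyclic loess the canonical Wnt targets (-0.11), ciliary margin (-0.20) and neural retina (-0.24) lists were lost, and median centring lost the same lists at -0.11, -0.20 and -0.24. Without the filter the canonical Wnt targets (-0.070), cell cycle (-0.052), ciliary margin (-0.17) and endothelial (-0.063) lists were lost. Without _x_at and _s_at probe sets the cell cycle (-0.063), ciliary margin (-0.18) and macrophage (0.086) lists were lost. A mean log2 of at least 6 lost the macrophage list (0.081), and averaging probe sets lost the ciliary margin list (-0.19). The Y-linked covariate lost the canonical Wnt targets (-0.048), cell cycle (-0.083), ciliary margin (-0.11), endothelial (-0.018), lens (-0.58), macrophage (0.12), neural retina (-0.21) and RPE identity (-0.13) lists. Leaving out an array gave shifts of -0.15 to -0.062 for canonical Wnt targets, -0.11 to -0.074 for cell cycle, -0.29 to -0.11 for ciliary margin, -0.16 to -0.044 for endothelial, -1.18 to -0.046 for lens, 0.088 to 0.15 for macrophage and -0.39 to -0.078 for neural retina. The cause of these losses was not tested.

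Lists that did not pass turned as follows. Array weights gave -0.014 for axon guidance, -0.12 for erythroid, -0.0037 for lysosome, 0.0017 for periocular mesenchyme and -0.035 for surface ectoderm. Leaving out both replicate 1 arrays gave -0.012 for axon guidance, -0.14 for erythroid, -0.0034 for lysosome, 0.014 for periocular mesenchyme and -0.030 for surface ectoderm. The Y-linked covariate gave 0.0031 for cell junctions, -0.028 for lysosome, -0.51 for sex-linked transcripts and -0.11 for the unfolded protein response. A mean log2 of at least 6 gave -0.017 for lysosome and -0.00079 for the unfolded protein response, and averaging probe sets gave -0.00011 and -0.015. The lysosome list gave -0.0039 without _x_at and _s_at probe sets. Without the filter, oxidative stress gave 0.0017 and periocular mesenchyme 0.030, and cyclic loess gave the latter 0.018. Leaving out an array gave -0.11 to 0.11 for erythroid, -0.036 to 0.037 for lysosome, -0.054 to 0.026 for periocular mesenchyme, -0.088 to 1.62 for sex-linked transcripts, -0.046 to 0.19 for surface ectoderm and -0.078 to 0.088 for the unfolded protein response. Without the filter, limma gave 0 of 45037 probe sets past the adjusted threshold (smallest adjusted p = 0.844). Signal near background may limit what the arrays resolve for dim probe sets, which was not tested.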

Other observations

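Genes in this paragraph were chosen after their values were seen. The transcription factor genes Alx1, Foxl2, Osr1, Osr2, Shox2 and Ebf2 were higher in albino pools in each of the 3 differences between arrays of the same number. Skeletal muscle markers were higher in the same differences, by 1.86, 2.16 and 0.54, and whether these genes follow muscle content was not tested. Alx1 stood at 9.38 ± 0.26 in albino and 8.60 ± 0.26 in pigmented pools, Foxl2 at 9.72 ± 0.20 and 8.99 ± 0.26, and Osr1 at 8.12 ± 0.32 and 7.02 ± 0.52 (SD, n = 3 each). Osr2 differed by 1.12 (SE 0.18), Shox2 by 1.09 (SE 0.19) and Ebf2 by 1.5 (SE 0.28). None passed in limma (adjusted p = 0.706 for Alx1 and 0.763 for Osr1), and a batch block for replicate 1 gave adjusted p = 0.0723 for both. Transcription factor genes of the fixed periocular mesenchyme list had other values, with Twist1 at -0.25, Foxc2 at -0.25, Foxc1 at -0.13, Prrx1 at -0.07 and Snai2 at 0.013. Of its collagen genes, Col3a1 (0.23), Col6a1 (0.12), Col1a2 (0.11) and Col6a2 (0.05) had values above 0 and Col1a1 (-0.15) below. Tmeff2 (1.11), Lepr (0.61) and Cdkn1a (0.89) were also higher, and Slc11a1 (-0.66) was lower.

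The tests of muscle markers, of replicate 1 and of sex make-up described next were chosen only after the results were seen, while the counts over other splits and the test of linkage to Tyr were planned, the latter with its bound on the ratio set after the result was seen.

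Muscle transcripts were higher in albino pools (list mean 1.52), and the protocol describes removal of tissue outside the eye. A lower share of RPE cells would raise every other cell type alike. The highest median among the 9 other marker lists was 0.16 (macrophage) and the lowest -0.83 (lens, resting on albino replicate 3). The muscle median was 1.61 (SD of members 0.34). Muscle was picked as the list with the largest difference, so its place above the others was fixed in advance. The medians show only that no rise of all types alike was seen. Extraocular muscle carried along in amounts that differ from pool to pool may account for the pattern and stays open. Its test decides nothing, since it compared the arrays with the highest and lowest list mean of each genotype, and 12 of 12 markers were higher in pigmented replicate 3 than 2 and in albino replicate 2 than 3 (medians 1.02 and 0.72). A change of muscle transcripts with the genotype also stays open and cannot be told apart from carried-over tissue, since no value analysed here separates them and the exact permutation p of 0.1, the smallest that 3 pools against 3 allow, bears only on chance.

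Both replicate 1 arrays stood apart from the other arrays. A separate labelling or hybridization run is a candidate explanation that the spike-in controls did not settle. Its test asked both sets of controls to move by over 1 log2 unit, and only 1 set did. A separate run that moved only 1 set would fail that test too, so the test cannot decide. The 18 probe sets of the BioB, BioC, BioD and Cre controls were higher on replicates 2 and 3 than on replicate 1 by a median of 2.37 in albino and 2.08 in pigmented arrays, while the 24 of the Dap, Lys, Phe and Thr controls were lower there, with medians of -0.34 and -0.24. On replicate 3 against replicate 2 the BioB, BioC, BioD and Cre controls were higher by medians of only 0.225 in albino and 0.205 in pigmented arrays. Spike-in controls are not tissue RNA, so this set marks a technical difference of the replicate 1 arrays, at a step not identified here. RNA degradation could add to the distance of replicate 1 and was not settled. The 3' minus 5' difference of the actin and Gapdh controls was higher on replicate 1 by 0.17 in albino and 0.31 in pigmented arrays. Both kinds of controls also lay to the same side in every albino and pigmented pair of the same number, some by little, which was not tested. The 3' minus 5' difference was higher on the pigmented array at each replicate number, at 1.105 against 0.87, 0.74 against 0.71 and 0.845 against 0.695. Medians of the BioB, BioC, BioD and Cre controls, albino minus pigmented, were -0.38, -0.12 and -0.09. A biological difference between the replicate 1 pools and the others, such as litter or stage, was not tested.

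Xist and Y-linked levels differed between pools. Xist stood at 10.95, 11.18 and 4.47 on the albino arrays and 11.23, 12.15 and 11.99 on the pigmented arrays, while the Y-linked mean was lowest on pigmented replicate 2 (2.32) and highest on albino replicate 3 (7.99). Pools with different numbers of female and male embryos may account for this, since 4 of 4 genes known to escape X inactivation were higher on the former array than on the latter by more than the median of 391 other X-linked genes (-0.05, SD 0.26), namely Kdm6a (0.66), Eif2s3x (0.59), Kdm5c (0.30) and Ddx3x (0.22). These 2 arrays also differ in genotype, which the comparison of escape genes cannot tell apart from sex make-up. Xist and Y-linked levels also differed between pools of the same genotype, which argues against genotype alone as their source. Y-linked means on the pigmented arrays were 7.39, 2.32 and 5.98, and Xist was low among the albino arrays on replicate 3 alone. Kdm6a was already among the genes with the smallest p on the lower side. It was lower by 0.35 on albino than on pigmented replicate 1, where Y-linked means were 7.47 and 7.39. A mislabelled or swapped pool was not tested.

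Counts were set against all 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. No split gave a probe set past the adjusted threshold in limma, so 10 of 10 reached the real count of 0 (highest other 0). At an unadjusted p under 0.05 the real split gave 1104 probe sets, 5 splits reached that count and the highest other gave 4379. The 4 splits that kept both replicate 1 arrays together gave 2811 to 4379, which points to the structure of the arrays described for replicate 1. Among the splits that part all 3 pairs, the real split gave 1104 and the others at most 295, and with the replicate block 4243 against at most 1238. For gene lists the real split gave 11, only 1 split reached that count, and the highest other gave 10.

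Variants linked to Tyr were tested as a source of the genes with the smallest p. The odds ratio of 0.638 for lying within 20 Mb of Tyr had an interval up to 2.37, past the bound of 2, which leaves linkage near Tyr open. Over the whole chromosome the ratio was 1.15 with an interval of 0.651 to 1.90. The bound was set for the 20 Mb window, and genes far from Tyr dilute a local effect, so this ratio does not exclude linkage. Fisher's exact test also treats genes as independent, while muscle genes among those with the smallest p varied together.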
